A study of Equus caballus with 6 samples.

How the data were processed

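RNA was sequenced from horse (Equus caballus) blastocysts collected on day 8 from mares treated to release several oocytes. Per the labels' protocols, blastocysts were treated with the protease mix Pronase, pieces of trophectoderm (TE, the outer epithelium that forms the placenta) were separated mechanically, and the inner cell mass (ICM, the cells inside it) was cleaned by immunosurgery, in which antibody and complement lyse the outer cells. RNA was isolated with a Picopure kit, amplified with a Nugen Ovation kit and made into TruSeq DNA libraries. The labels name version V1 of the Ovation kit for the samples and V2 for the series, so its version is open. The 6 libraries are 3 of ICM (labelled 15, 22 and 25) and 3 of TE (labelled 16, 23 and 24), taken from the titles. No number occurs in both groups and nothing in the labels ties an ICM to a TE of the same blastocyst, so the groups were compared without pairing. The labels speak of parts of individual blastocysts, without naming the mares, so p-values measure the spread between these libraries.

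The authors deposited 1 table with 12270 rows, and its header gives the 6 library columns as RPKM (reads per kilobase of gene, scaled for sequencing depth). Per the submitters' processing notes, FastQC and DESeq were used, with no version. The aligner, the counter, the genome build and the annotation are not given in the sources used here. The deposited table also holds the mean signal of each gene over the 6 libraries (baseMean, per the file headers a mean of DESeq's normalized counts), the fold between the tissues as a ratio, its log2 value, and DESeq's p-value and adjusted p-value, all made by the authors. The deposited fold equals the mean RPKM of ICM over that of TE to a relative difference of at most 2.87e-08. Every row has at least 0.4 RPKM in at least 2 libraries, so genes below that level in both tissues were not analysed here.

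The deposited RPKM and baseMean together give back the reads behind each value. Their quotient is 1 factor per gene, and RPKM times this factor was a whole multiple of 1 step per library, within 0.001 reads, for 100% of the values of up to 1000 reads in every library. The gene lengths that follow were whole numbers of bases within 0.01 for 100% of the rows. The libraries had been scaled with size factors to 1 common constant, not with their own totals. The reads in the genes of the table came to 7972431, 10686659 and 6622207 for ICM 15, 22 and 25 and 8939068, 6526212 and 9812871 for TE 16, 23 and 24. These reads come from amplified cDNA without molecular identifiers, so counting errors and floors understate the true error.

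Gene symbols were used as deposited. Among the rows, 9460 had a symbol that the NCBI gene table of assembly TB-T2T also lists, 67 an older symbol and 449 a numbered locus that matched it. That table was used only for names. In 20 rows a spreadsheet had turned the symbol into a date, and 258 rows share a symbol with another row, often as parts of 1 gene, so single values of these are uncertain. Coordinates are those of the deposited table, whose build is not named. Strand was not stated, so reads of overlapping genes on opposite strands cannot be told apart.

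For the comparison, genes with at least 1 RPKM in at least 3 libraries were kept (9436). Log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. A log2 difference is ICM minus TE on this scale, which understates the change of low genes, and its error is the standard error (SE). RPKM are given as mean ± SD over 3 libraries. Where a tissue had 0 reads, a fold was bounded with a floor of 3 reads over the group. In the simulation of ICM against TE with 9468 genes tested, the test recovered 1 of 47 genes changed 2-fold, 30 of 49 changed 4-fold, 40 of 49 changed 8-fold and 43 of 50 changed 16-fold, none with the wrong sign, and called 12 of 9273 unchanged genes. It drew genes independently, with the same spread of a gene in both tissues. The real ICM libraries spread 2.35 times as much as those of TE and include an outlying library, so these rates may not hold for the data.

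Before the data were examined, 32 gene lists were fixed, covering the lineages of the blastocyst, signalling, metabolism, stress and other cell types that the dissection could hold. The 28 lists with at least 5 members kept were tested with camera at a preset correlation of 0.01, adjusted over these lists. Camera compares the mean statistic of the members with that of all other genes. Camera with an estimated correlation and fry were run beside it, and members called were also counted after adjustment over the list alone. Genes were named by a rule fixed at the same time: the 6 genes with the largest called difference in each direction whose ICM and TE values did not overlap; the 4 members with the smallest p in each list past the threshold and in the 3 lineage lists, and 2 members of other lists that held a call; and a fixed set of lineage genes. Genes named outside this rule are marked as chosen after their values were seen. EOMES, KRT8, KRT18 and SOX17 belong to the fixed set and were not analysed here. Some genes that the rule names, and a list past the threshold, are not reported here.

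The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 RPKM, rescaling by the median of ratios, quantile normalization, robust moderation, no trend, library weights, and leaving out each library. The use of limma-voom on the recovered reads, with all libraries and without ICM 25, was added after seeing the data. Numbers of detected genes were compared with exact permutation tests in scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.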

Results

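The transcriptomes of the 2 tissues of the day 8 horse blastocyst were measured in 3 ICM and 3 TE libraries. Between 6526212 and 10686659 reads per library fell in the genes of the table, and the 20 genes with the most reads took 17.9% to 22.7% of them. At 1 RPKM or more, 9309 ± 249 genes were detected in ICM and 9167 ± 138 in TE (mean ± SD, n = 3 each), a difference of 142 genes (exact permutation test, two-sided, p = 0.5, where 0.1 is the smallest p that 3 against 3 allows). At 5 RPKM the difference was -310 genes (exact permutation p = 0.6), so its direction turned with the threshold. The turn rested on ICM 25, with 4370 genes at 5 RPKM. ICM 15 and 22 had 5213 and 5536, and the TE libraries 5226 to 5495.

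The TE libraries resembled one another more than the ICM libraries did. Pearson correlations across the 9436 genes kept, which are not independent replicates, were 0.976 to 0.980 between TE libraries, 0.942 between ICM 15 and 22, and 0.864 and 0.895 between ICM 25 and these. With TE 16, 23 and 24, ICM 25 correlated at 0.902, 0.904 and 0.897, slightly above its values with the other ICM libraries. The median SD of a gene within a group was 0.44 log2 units in ICM and 0.19 in TE, and 0.25 in ICM without ICM 25. The first principal component, with 38.9% of the variance, set ICM 25 apart from the other 5 libraries, and the second, with 37.5%, separated the tissues.

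**Figure D1:**
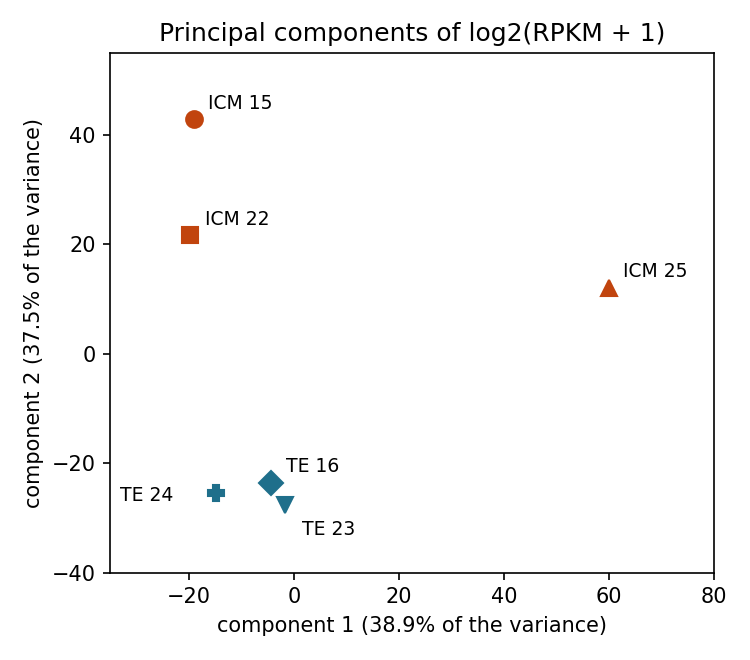
Each point is 1 library of ICM (orange) or TE (blue), placed by the first 2 principal components of log2(RPKM + 1) over 9436 genes, with the share of variance of each component on its axis. ICM 25 lies at 59.9 on the first component, where the other 5 libraries lie between -19.8 and -1.71.

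The comparison of ICM with TE asked which genes differ between the tissues as isolated. Tissue and isolation method (immunosurgery for ICM, mechanical for TE) coincide, so they cannot be told apart for any gene below. Genes higher in ICM were led by GPNMB, a membrane glycoprotein, at 38.3 ± 26.8 RPKM against 0.64 ± 0.19 in TE (log2 difference 4.17, SE 0.65, limma adjusted p = 0.025). They also included CYP1B1, a cytochrome P450 (18.2 ± 15.1 against 0.05 ± 0.02 RPKM), the smooth muscle actin ACTG2 (22.5 ± 17.1 against 0.20 ± 0.07), the glypican GPC4 (15.3 ± 11.02 against 0.09 ± 0.10), the secreted phosphoprotein SPP1 (13.8 ± 10.7 against 0.09 ± 0.07) and the homeobox repressor TGIF1. TGIF1 was the least variable of these in ICM, at 26.1 ± 1.61 RPKM against 1.83 ± 0.60 (log2 difference 3.28, SE 0.25, adjusted p = 0.0032).

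Genes higher in TE were led by transcription factors. GATA3, a regulator of trophoblast, stood at 32.9 ± 3.26 RPKM in TE against 4.07 ± 2.09 in ICM (log2 difference -2.84, SE 0.34, limma adjusted p = 0.014). TFAP2A stood at 33.7 ± 6.96 against 5.31 ± 1.27 RPKM (log2 difference -2.46, SE 0.27, adjusted p = 0.013). The homeobox gene DLX5 was at 17.8 ± 0.69 against 2.58 ± 1.30 and the zinc finger factor EGR2 at 20.6 ± 6.35 against 3.35 ± 2.77 RPKM. The retinol dehydrogenase family member DHRS9 (10.6 ± 2.44 against 1.23 ± 0.53) and the small GTPase RAB39A (11.04 ± 1.83 against 1.56 ± 0.21) completed the 6. In the deposited coordinates, whose build is not named, GATA3 lies on chromosome 29 (26022567 to 26039578), TFAP2A on chromosome 20 (10290290 to 10307429), GPNMB on chromosome 4 (54828594 to 54853962) and TGIF1 on chromosome 8 (43702878 to 43710779).

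In all, 176 of 9436 genes were called (limma, adjusted p at 0.05), 88 higher in ICM and 88 higher in TE, and 1592 had an unadjusted p under 0.05. The values of the 3 ICM and 3 TE libraries did not overlap for 24.6% of the genes tested, where chance gives 10%. The median log2 difference over all genes tested was -0.15. Without ICM 25 it was -0.01, and with any other library left out -0.26 to -0.11, so this shift rested largely on ICM 25. With all libraries the median was -0.03 after rescaling by the median of ratios, which called 129 genes higher in ICM and 84 higher in TE, and -0.03 after quantile normalization, which called 129 and 77. A filter of 5 RPKM gave 29 and 52. The count hung on single libraries: it was 18 without ICM 15, 76 without ICM 22 and 1086 without ICM 25 (556 higher in ICM and 530 in TE), and 0, 1 and 1 without TE 16, 23 and 24. In the fit without TE 16, which called 0 genes, 983 had an unadjusted p under 0.05.

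Of the 28 lists tested, 14 passed with a preset correlation. None held with an estimated correlation (lowest adjusted p = 0.372) or by fry in a single direction (lowest adjusted p = 0.10). Calls of members over all genes fell to 0 in these lists without any 1 of the TE libraries, and without ICM 15 in all but the trophectoderm list, which kept 2. Genes of the epiblast, the pluripotent part of the ICM, were higher in ICM as a list (21 members tested, camera adjusted p = 0.00063). The list's adjusted p was 0.398 with an estimated correlation. Among its members 5 were called higher in ICM and 0 higher in TE, and 5 and 1 when adjusted over the list alone. The 5 calls became 3 with a pseudocount of 0.1, 1 with no filter or a filter of 5 RPKM, and 8 with library weights. The homeobox factor NANOG stood at 9.43 ± 6.71 RPKM in ICM and 0.12 ± 0.07 in TE (log2 difference 2.88, SE 0.57, limma adjusted p = 0.046). KLF4 was at 7.92 ± 1.05 against 2.14 ± 0.13 RPKM, GDF3, a TGF-beta family ligand, at 2.25 ± 1.51 against 0.02 ± 0.04, and the ETS factor ETV4 at 3.61 ± 1.39 against 0.79 ± 0.03. SOX2 stayed below the filter: its ICM libraries 15, 22 and 25 had 84, 115 and 10 reads and its TE libraries 0, so that ICM was at least 60.4-fold higher against a floor of 3 reads over the group. POU5F1, the core pluripotency factor, was abundant in both tissues, at 76.9 ± 35.7 RPKM in ICM and 44.2 ± 10.3 in TE, and was not called (adjusted p = 0.44). ICM 25 held 36.0 RPKM of POU5F1 and 1.75 RPKM of NANOG, where ICM 15 and 22 held 93.1 and 102 of POU5F1 and 14.1 and 12.4 of NANOG. Without ICM 25, 12 members were called higher in ICM and 1 higher in TE, and POU5F1 passed (log2 difference 1.15, limma adjusted p = 0.018).

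**Figure D2:**
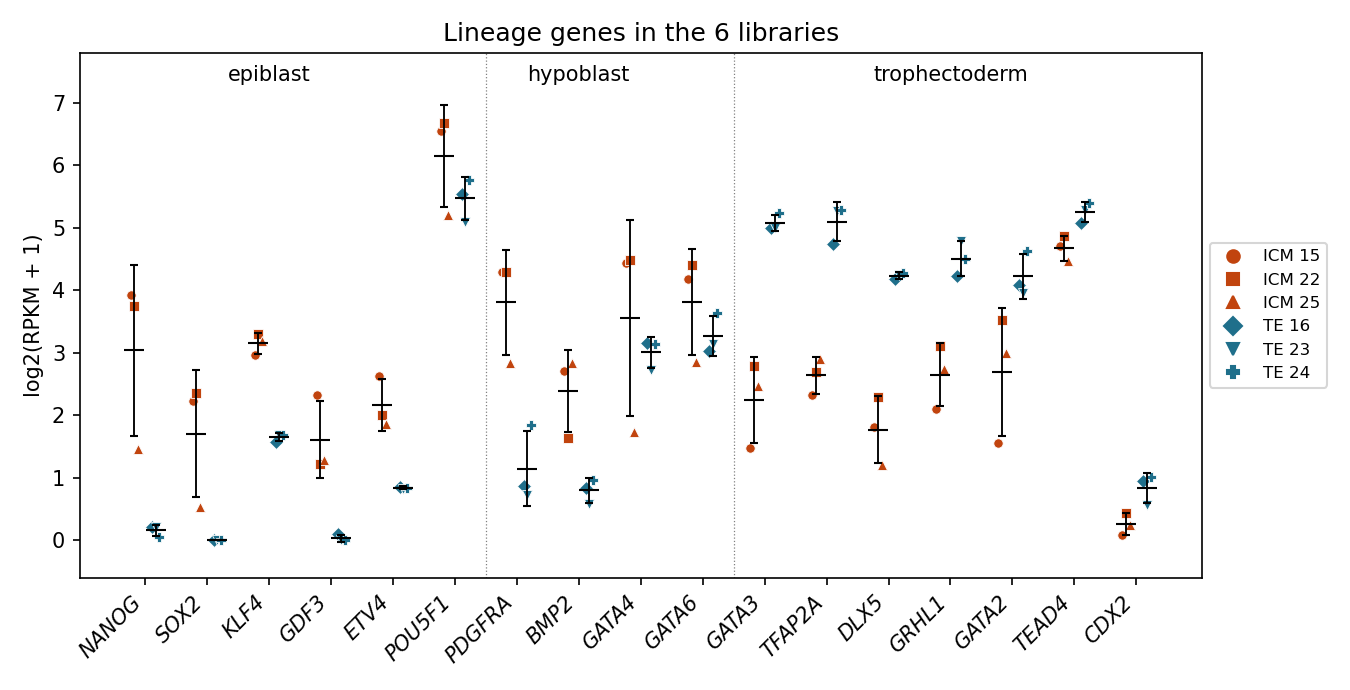
Expression of 17 lineage genes as log2(RPKM + 1), with 1 symbol per library, ICM in orange and TE in blue, and black bars for the mean and SD of the 3 libraries. NANOG lies at 14.1, 12.4 and 1.75 RPKM in ICM and at 0.157 or less in TE, and GATA3 at 30.9 to 36.6 RPKM in TE and 5.88 or less in ICM.

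The hypoblast list, for the endoderm layer that lines the blastocyst cavity, was higher in ICM (30 members, camera adjusted p = 4.1e-06, and adjusted p = 0.372 with an estimated correlation). Its calls were 3 higher in ICM and 0 higher in TE, or 6 and 1 when adjusted over the list alone. Those higher in ICM became 1 with a filter of 5 RPKM, 5 with either rescaling and 8 with library weights. The 3 were the growth factor receptor PDGFRA (14.5 ± 7.22 against 1.35 ± 1.06 RPKM, limma adjusted p = 0.032), the collagen chaperone SERPINH1 (1.70 ± 0.21 against 0.12 ± 0.13) and the coactivator CITED1 (2.04 ± 0.89 against 0.06 ± 0.05). BMP2 was at 4.59 ± 2.16 against 0.75 ± 0.23 RPKM and missed the threshold (adjusted p = 0.056). GATA4 (14.8 ± 10.8 against 7.11 ± 1.31) and GATA6 (14.6 ± 7.41 against 8.78 ± 2.26), which specify the endoderm, were not called (adjusted p = 0.73 and 0.55). ICM 25 held 2.33 RPKM of GATA4, below the 5.60 to 7.93 of the TE libraries. Without ICM 25, 14 members were called higher in ICM and 2 higher in TE, GATA4 (limma adjusted p = 0.0065) and GATA6 (adjusted p = 0.027) among the first.

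The trophectoderm list was higher in TE (22 members, camera adjusted p = 0.0020, and adjusted p = 0.372 with an estimated correlation). GATA3, TFAP2A, DLX5 and GRHL1, a grainyhead factor of epithelia (22.0 ± 4.43 RPKM in TE against 5.53 ± 2.15 in ICM), were its 4 calls, none was called higher in ICM, and 10 and 1 passed when adjusted over the list alone. With median of ratios rescaling 1 member was called higher in ICM, and 7 and 2 passed over the list alone; with quantile normalization 6 and 1 did. GATA2 was at 18.1 ± 4.98 RPKM in TE against 6.49 ± 4.33 (limma adjusted p = 0.15) and TEAD4 at 37.3 ± 4.21 against 24.7 ± 3.51 (adjusted p = 0.26). TFAP2C had similar means, 10.2 ± 0.83 RPKM in TE and 10.4 ± 6.15 in ICM (log2 difference -0.16, SE 0.42, limma adjusted p = 0.90). This rested on ICM 25, at 3.86 RPKM, where ICM 15 and 22 held 11.2 and 16.1 and the TE libraries 9.24 to 10.8. CDX2, which acts in trophectoderm, stayed below the filter with 16, 6 and 17 reads in TE and 1, 7 and 3 in ICM, or 0.80 ± 0.29 against 0.20 ± 0.15 RPKM.

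The list for fibroblast growth factor (FGF) and ERK signalling passed with ICM higher (17 members, 10 with a higher mean in ICM, camera adjusted p = 0.0028, and adjusted p = 0.372 with an estimated correlation), with 4 calls higher in ICM and 0 in TE, and the same numbers when adjusted over the list alone. They were the phosphatase DUSP5 (8.83 ± 3.95 against 1.90 ± 0.60 RPKM, limma adjusted p = 0.047), the inhibitor SPRY4 (4.39 ± 1.97 against 0.84 ± 0.14) and the ETS factors ETV4 and ETV5 (3.91 ± 1.65 against 0.62 ± 0.37). The 4 calls became 1 with a pseudocount of 0.1 and 0 with no filter. With a filter of 5 RPKM, which drops these low genes, the list no longer passed (adjusted p = 0.98). The NODAL and BMP list passed with ICM higher (18 members, camera adjusted p = 0.0053, and adjusted p = 0.398 with an estimated correlation). It had GDF3 as its call, lost with no filter and with quantile normalization, and 2 higher in ICM and 1 in TE when adjusted over the list alone (5 and 1 with either rescaling). SMAD1 (5.53 ± 1.05 in ICM against 12.9 ± 0.46 RPKM, limma adjusted p = 0.054) and ID2 (38.5 ± 20.7 against 13.8 ± 2.71, adjusted p = 0.17) lay on opposite sides. The JAK-STAT and LIF list passed with ICM higher (16 members, camera adjusted p = 0.0043, and adjusted p = 0.372 with an estimated correlation). It had KLF4 as its call, also when adjusted over the list alone (3 members with either rescaling). The receptor subunit IL6ST (5.96 ± 3.10 against 1.64 ± 0.17 RPKM), JAK2 (8.75 ± 4.66 against 3.57 ± 0.50) and PIM1 (3.48 ± 2.42 against 1.07 ± 0.32) were not called. ETV4, ETV5, GDF3 and KLF4 also belong to the epiblast list and are among its calls, so they are not separate results here.

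Cholesterol synthesis showed the lowest camera p of the 28 lists, with TE higher (24 members, adjusted p = 1.3e-06, and adjusted p = 0.372 with an estimated correlation). The median log2 difference of its members was -0.87 and 1 of 24 had a higher mean in ICM. STARD4, which carries sterols between membranes, was the call over all genes (10.8 ± 3.11 in ICM against 28.7 ± 3.62 RPKM in TE, limma adjusted p = 0.047), and 13 members passed, all higher in TE, when adjusted over the list alone (0 without any 1 of the TE libraries). STARD4 missed the threshold with a pseudocount of 0.1 (0.055), no filter (0.059), a filter of 5 RPKM (0.053) and either rescaling (0.060 and 0.065). IDI1 (24.9 ± 5.96 against 52.9 ± 3.89), HSD17B7 (21.4 ± 8.78 against 55.8 ± 7.82) and INSIG1 (5.54 ± 1.10 against 11.8 ± 0.29) had adjusted p of 0.069, 0.077 and 0.079. SOAT1, which esterifies cholesterol and stands in another list, went the other way (21.7 ± 3.40 against 7.53 ± 0.99 RPKM, adjusted p = 0.032).

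The ion and water transport list, for the pumping of fluid into the blastocyst cavity, passed with TE higher (18 members, camera adjusted p = 0.010, and adjusted p = 0.403 with an estimated correlation) with 0 members called over all genes and 4, all higher in TE, when adjusted over the list alone, of which 0 were left with median of ratios rescaling or quantile normalization. The proton pump subunit ATP6V1B1 (5.91 ± 2.49 in ICM against 20.1 ± 5.10 RPKM, limma adjusted p = 0.051), the sodium channel subunits SCNN1A (5.09 ± 3.53 against 17.5 ± 3.48) and SCNN1B (2.67 ± 1.11 against 8.14 ± 3.38) and the exchanger SLC9A2 (0.44 ± 0.26 against 2.52 ± 1.33) had the smallest p. The list missed the threshold without ICM 15 (adjusted p = 0.059) and with a filter of 5 RPKM (0.24). The 13 mitochondrially encoded genes all had lower means in ICM (camera adjusted p = 0.0088, and adjusted p = 0.403 with an estimated correlation). None was called, also when adjusted over the list alone, and MT-CYB was at 3312 ± 966 RPKM against 6581 ± 2058. Mitochondrial genes took 10.5% ± 2.17 of the reads in ICM and 13.2% ± 0.85 in TE (n = 3 each, exact permutation p = 0.2). This list missed the threshold without ICM 22 (adjusted p = 0.079).

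The list of epithelial junctions and polarity passed with ICM higher (33 members, median log2 difference 0.13, camera adjusted p = 0.0088, and adjusted p = 0.372 with an estimated correlation). It had 1 call, the junction protein JUP (22.8 ± 2.50 in ICM against 9.46 ± 1.31 RPKM, limma adjusted p = 0.045), and 2 higher in ICM and 1 in TE when adjusted over the list alone. JUP missed the threshold with a pseudocount of 0.1 (0.052) and no filter (0.053). ESRP2, a splicing factor of epithelia, was at 5.71 ± 0.52 against 13.3 ± 2.17 RPKM. The matrix and mesenchyme list (9 members, camera adjusted p = 0.00055, and adjusted p = 0.372 with an estimated correlation) lay higher in ICM, with 5 members higher in ICM and 1 in TE when adjusted over the list alone, but its 1 call, the receptor PDGFRB, was higher in TE (0.90 ± 0.22 against 4.78 ± 0.72 RPKM, limma adjusted p = 0.022). Either rescaling added 2 calls higher in ICM and library weights 4. THY1 (1.89 ± 0.83 against 0.17 ± 0.22), TIMP1 (82.4 ± 47.2 against 27.6 ± 4.82) and ITGAV (4.02 ± 0.82 against 1.74 ± 0.14) were not called. The 50 cytosolic ribosomal proteins passed with higher values in ICM relative to all genes (camera adjusted p = 0.0088, and adjusted p = 0.788 with an estimated correlation), with 0 calls, also when adjusted over the list alone, and a median log2 difference of 0.09, which was 0.23 with median of ratios rescaling, 0.38 with library weights, 0.34 without ICM 25 and 0.28 without TE 24. Leaving out ICM 22 turned this median to -0.17 and leaving out TE 23 to -0.02, and ended the call (adjusted p = 0.19 and 0.16), as did no filter (0.079). The epithelial list missed the threshold without ICM 25 (adjusted p = 0.42, and 0.35 by voom) and with library weights (0.18).

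**Figure D3:**
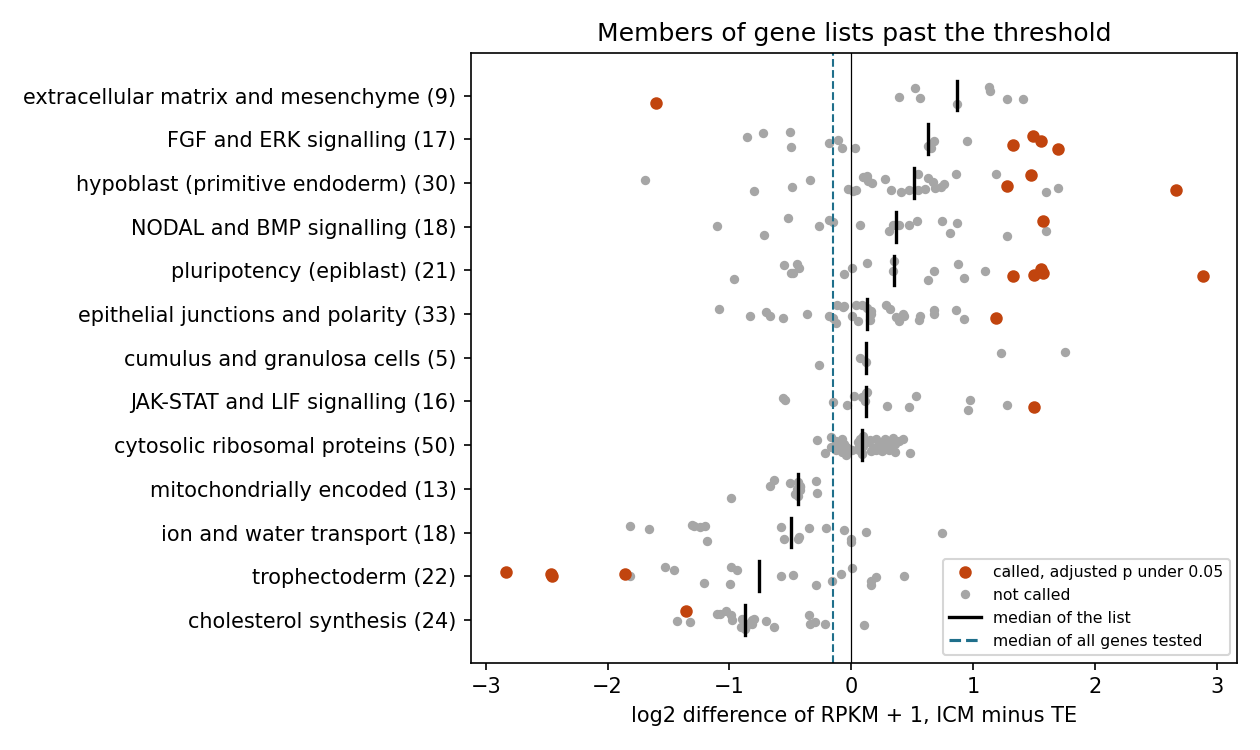
Log2 differences, ICM minus TE, of the tested members of the lists past the threshold that are reported here, with the number of members in parentheses; each dot is 1 gene, orange where called, and black bars are list medians. The medians run from -0.87 for cholesterol synthesis to 0.87 for matrix and mesenchyme, beside -0.15 for all genes tested (dashed).

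Among the 14 lists that did not pass, 7 held calls. The immediate-early list had 3 members called higher in TE, among them EGR2 and the phosphatase DUSP1 (14.8 ± 4.38 RPKM in TE against 3.47 ± 1.55, limma adjusted p = 0.038), and 0 higher in ICM (14 members, camera adjusted p = 0.20). Adjusted over the list alone, 6 were higher in TE and 2 in ICM. PTGS2, the inducible enzyme of prostaglandin synthesis, was at 175 ± 65.0 RPKM in TE against 41.0 ± 10.98 in ICM (adjusted p = 0.029), in a list with a camera adjusted p of 0.59. The endocytic adaptor DAB2 was at 142 ± 12.4 against 32.8 ± 10.8 RPKM (limma adjusted p = 0.019), and its receptor partner LRP2 at 213 ± 11.2 against 72.1 ± 37.5 (adjusted p = 0.068), in the lysosome and endocytosis list (camera adjusted p = 0.18). In the Hippo list (camera adjusted p = 0.21) ANKRD1 was higher in ICM at 16.2 ± 3.78 against 2.65 ± 2.09 RPKM (limma adjusted p = 0.047), and LATS2 was at 4.31 ± 0.70 against 2.11 ± 0.50. ACSL4, which activates long fatty acids, was at 2.56 ± 1.01 in ICM against 0.04 ± 0.05 RPKM (adjusted p = 0.026), in the lipid list (camera adjusted p = 0.14). The heat shock list (camera adjusted p = 0.76) held SERPINH1, and STIP1 was at 41.9 ± 14.2 against 66.6 ± 11.05 RPKM. The steroid list (camera adjusted p = 0.66) held SOAT1 and DHRS9. Adjusted over the list alone, these lists had 3 (prostaglandin) and 2 (lysosome) members higher in TE, 1 higher in ICM (Hippo and heat shock), 1 in ICM and 3 in TE (lipid), and 2 on each side (steroid). The other lists had 0 calls (1, higher in TE, for the unfolded protein response when adjusted over the list alone) and camera adjusted p of 0.14 for cell cycle, imprinted genes and nuclear oxidative phosphorylation, 0.086 for the unfolded protein response, 0.21 for WNT signalling, 0.53 for DNA methylation and chromatin, and 0.59 for glycolysis. Some of these lists passed in other settings, all but imprinted genes and DNA methylation with TE higher. Without ICM 25 the lipid (camera adjusted p = 0.030), lysosome (0.00084) and unfolded protein (0.0097) lists passed, and with library weights the same (0.041, 0.0019 and 0.022). With no filter cell cycle (0.031), imprinted genes (0.014), nuclear oxidative phosphorylation (0.031) and the unfolded protein response (0.020) did. Cell cycle passed without ICM 15 (0.027), nuclear oxidative phosphorylation without ICM 22 (0.011) and the immediate-early list by voom (0.044). By voom without ICM 25, DNA methylation (0.044), lipid (0.022), lysosome (0.00019) and unfolded protein (0.0072) passed.

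Lists of other cells were checked, and their genes without a row were not analysed here. Of the blood and immune list 10 genes were in the table, 2 were tested and 0 called. The highest, LCP1, was named after its values were seen (5.83 ± 3.25 RPKM in ICM against 14.8 ± 4.55 in TE, limma adjusted p = 0.12). Of the oocyte and maternal list 5 were in the table, 1 was tested and 0 called. The list of muscle, neuron and skin genes, kept as a negative control, had 8 in the table, 4 tested and 0 called. The uterine and oviductal list had 8 in the table and 4 tested, with SPP1 as its 1 call and PGR at 0.67 ± 0.11 in ICM against 2.05 ± 0.35 RPKM in TE (limma adjusted p = 0.095). The cumulus and granulosa list passed with ICM higher (5 members, camera adjusted p = 0.032, and adjusted p = 0.372 with an estimated correlation), with 0 calls and 2, higher in ICM, when adjusted over the list alone. Its members with the smallest p were SERPINE2 (6.05 ± 6.38 against 0.60 ± 0.21 RPKM) and a row of VCAN (10.2 ± 5.03 against 3.52 ± 1.03), whose symbol is shared with another row. The steroidogenic genes STAR (23.7 ± 3.91 against 21.7 ± 3.66) and CYP19A1 (12.3 ± 12.003 against 12.8 ± 6.93 RPKM) did not separate the tissues. The list missed the threshold without ICM 25 (camera adjusted p = 0.30, and 0.28 by voom) and without TE 23 (0.054). It also did with median of ratios rescaling (0.051), quantile normalization (0.0501), library weights (0.12) and voom (0.074). With no filter the negative control list (0.031) and the uterine list (0.026) passed, higher in ICM.

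The authors' deposited table calls 2039 genes at an adjusted p under 0.05 with DESeq, 1308 higher in ICM and 731 higher in TE. Of the 1333 of these that were tested here, 175 are among the 176 genes called by limma from the same libraries. For 622 of the 2039 genes the ICM and TE values overlap. Per the authors' deposited table, POU5F1 passes with an adjusted p of 0.010, GATA4 with 0.0056 and SOX2 with 1.35e-16.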

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

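The use of limma-voom on the recovered reads was chosen after seeing the data, and the other settings beforehand. No paired analysis was possible because ICM and TE share no replicate number. By camera with the preset correlation, the lists for epiblast, hypoblast and trophectoderm kept their direction and their side of the threshold in all settings. With an estimated correlation, which was run in the main setting only, none of them passed (camera adjusted p = 0.398, 0.372 and 0.372). Cause was not tested where none is given.

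Against 176 genes (88 higher in ICM, 88 in TE), a pseudocount of 0.1 called 112, with 49 higher in TE. No filter called 114 (54 higher in TE), and a filter of 5 RPKM, with fewer genes tested, 81 (29 in ICM and 52 in TE). Library weights called 760 (365 and 395) and gave ICM 25 a weight of 0.172 where TE 23 had 2.81. Voom called 195 (125 and 70), and without ICM 25 it called 1335 (701 and 634). Leaving out 1 library, with fewer samples, gave 0 to 1086 genes, 0 to 556 higher in ICM and 0 to 530 higher in TE. The lists past the threshold numbered 14, and 11 to 19 over the settings. The difference in detected genes turned from 142 at 1 RPKM to -310 at 5 RPKM, and the ratio of the spread in ICM to that in TE was 2.35, and 2.39, 2.36 and 2.56 with pseudocounts of 0.1 and 0.5 and the filter of 5 RPKM.

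Some lists turned direction, with these adjusted p: FGF and ERK with the filter of 5 RPKM (0.985), glycolysis with no filter (0.991), heat shock with library weights (0.952), and steroid synthesis with no filter (0.653) and library weights (0.822). In voom without ICM 25, oxidative phosphorylation (0.875), prostaglandins (0.875) and steroid synthesis (0.737) turned. With 1 library left out, DNA methylation (0.980), lysosome (0.980) and heat shock (0.863) turned without ICM 15. Heat shock also turned without TE 24 (0.832). Oxidative phosphorylation (0.9498), prostaglandins (0.881) and steroid synthesis (0.709) turned without ICM 25. Over all fits with 1 library left out, turned or not, adjusted p ran from 0.0503 to 0.980 for DNA methylation and 0.558 to 0.881 for heat shock. It ran from 0.000837 to 0.980 for lysosome and 0.0107 to 0.9498 for oxidative phosphorylation, with TE higher at both low ends as with all libraries. For prostaglandins it ran from 0.403 to 0.881 and for steroid synthesis from 0.304 to 0.839. The log2 difference of TFAP2C turned with library weights (0.26), voom (0.069) and voom without ICM 25 (0.44), and ran from -0.54 to 0.37 with 1 library left out. That of CYP19A1 ran from -0.97 to 0.20 and that of STAR from -0.00082 to 0.24. Of 474 values of 79 named genes with 1 library left out, 141 lost the threshold, 29 gained it and 4 turned. Of 683 with all libraries in the settings fixed beforehand, 29 lost it, 36 gained it and 1 turned. Only genes called in the main fit could lose the threshold, and many named genes were not called there. The share lost among called genes is therefore larger than 141 of 474 or 29 of 683. Depth limits low genes: CDX2 rests on 1 to 17 reads per library.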

Other observations

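Of the tests below, the correlation with gene length was chosen before its result was seen, and all others after. Gene families were taken from their symbols, without partners that carry a family symbol. Of 168 solute carriers tested, 5 were called higher in ICM and 3 higher in TE (limma, adjusted over all genes), and the family did not pass (camera adjusted p = 0.35 over 10 families). The amino acid transporter SLC38A2 was at 84.5 RPKM in ICM and 12.4 in TE (log2 difference 2.62, SE 0.33, adjusted p = 0.014), with SLC16A4, SLC2A5 and SLC4A7 among those on the same side. SLC16A6 was at 3.99 RPKM in ICM and 20.2 in TE (log2 difference -2.21, SE 0.36, adjusted p = 0.028), with SLC35A1 and the iron exporter SLC40A1 on its side. Integrins (6 tested) and serpins (9) were higher in ICM and 70 mitochondrial ribosomal proteins higher in TE by camera (adjusted p = 0.0014, 0.024 and 0.019), and with an estimated correlation these had adjusted p of 0.17, 0.50 and 0.95. Among the serpins SERPING1 (9.42 against 2.40 RPKM) and SERPINH1 were called.

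ICM 25 lies apart from the other 5 libraries by correlation and first component, and 29 genes kept there exceed 4 times the highest value of every other library, against 5 for ICM 15, 1 for ICM 22 and 0 for each TE library; 146 of ICM 15, 89 of ICM 25, 11 of ICM 22 and 4 to 17 of each TE library lie more than 4 times under the lowest. Among those above in ICM 25 are GPRC5A (157 RPKM, at most 26.9 elsewhere), ECM1 (108, at most 10.3) and CYP17A1 (31.7, at most 5.17), while MYCN (4.45, at least 18.7) and HIST1H1A (5.51, at least 36.5) lie below. Trophectoderm carried into this ICM would put no gene far above both tissues, so the 29 genes argue against it as the whole account. Of the genes called without ICM 25, the 556 higher in ICM moved a median of 0.931 of the way toward TE (95% bootstrap interval over genes 0.886 to 0.979). The 530 higher in TE moved by 0.275 (0.218 to 0.323). These fractions were taken without rescaling, where ICM 25 had a median of ratios factor of 0.775 and the other libraries 1.02 to 1.14. A lower scale alone makes such fractions unequal, so they cannot decide. Carry-over together with another difference stays open. Low depth is argued against by TE 23, which has fewer reads and correlates at 0.976 with its group. A length bias is argued against as the whole account: with the length trend of every library removed, ICM 25 still correlated at 0.865 (95% bootstrap interval over genes 0.857 to 0.872) and 0.896 (0.890 to 0.902) with ICM 15 and 22, and these at 0.943 (0.939 to 0.947) with each other. The rank correlation of the deviation with length, 0.0819 (0.0626 to 0.102), is however not clear of the bound of 0.1 set beforehand (0.131 between ICM 15 and 22). All intervals in this paragraph resample genes, which are not independent, and hold no spread between libraries. No biological explanation was tested, as the labels divide the ICM no further.

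CYP1A1, CYP1B1 and TIPARP, textbook targets of the aryl hydrocarbon receptor, were called higher in ICM in 3 of 3 libraries. CYP1A1 was at 4.21 RPKM in ICM and 0.01 in TE (log2 difference 2.35, SE 0.24, limma adjusted p = 0.013) and TIPARP at 30.1 and 8.89 (log2 difference 1.65, SE 0.23, adjusted p = 0.020). More general handling stress in ICM than in TE stays open: the immediate-early list had 3 members called higher in TE, but 5 of 14 had a higher mean in ICM and its camera adjusted p was 0.20 (0.044, with TE higher, by voom). A wider response of the receptor's targets may still be present, since the 6 other targets tested had a camera p of 0.148 with 0 called, which decides nothing, and the receptor's own gene, AHR, was at 2.10 RPKM in ICM and 4.37 in TE (limma adjusted p = 0.21). Tissue and isolation method (immunosurgery for ICM, mechanical for TE) cannot be told apart here.

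XIST, the RNA of the inactive X chromosome, is called higher in ICM in the authors' deposited table (adjusted p = 1.55e-06) but not by limma (adjusted p = 0.56). It stood at 0.70, 71.0 and 69.6 RPKM in ICM 15, 22 and 25 and at 53.7, 0.03 and 0.35 in TE 16, 23 and 24. A difference between the tissues is argued against by TE 16, which held 76.9 times the level of ICM 15. Libraries from embryos of different sexes are a candidate explanation, as both levels, 76.9 times apart, occur in each tissue and the high libraries lie within 1.32 times of one another. The median RPKM of X-linked genes over that of autosomal genes was 1.13, 0.99 and 1.04 in ICM 22, ICM 25 and TE 16. In ICM 15, TE 23 and TE 24 it was 0.95, 0.83 and 0.83. The levels are not balanced between the tissues, which limits the reading of X-linked genes. For GPC4, ICM lay above TE at either XIST level. Where XIST was low, GPC4 was at 22.9 RPKM in ICM 15 and at 0.05 and 0.20 in TE 23 and 24. Where XIST was high, it was at 20.3 and 2.64 in ICM 22 and 25 and at 0.02 in TE 16. The labels give no sex, and a pairing of neighbouring numbers as 1 embryo (15 with 16, 22 with 23, 24 with 25) would join a high with a low library each time.

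Among the 10 splits of the 6 libraries into 3 and 3, the true one called 176 genes and the highest other 2. It called 14 lists, and the highest other 10. In both cases 1 split, the true one, reached the value, and 10 splits are too few for a share under 0.05. Each other split holds both tissues on both sides, so a tissue difference widens its spread and few gene calls there decide nothing. The other splits called 2 to 10 lists, so camera with the preset correlation passed lists on mixed groupings too.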
